A study of Mus musculus with 8 samples.

How the data were processed

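Single-cell RNA sequencing was done on cells from the arcuate nucleus (ARC) and the medial preoptic area (MPOA) of the mouse hypothalamus. Per the labels, the mice were 14-week-old C57BL/6 females, either virgins or lactating mothers, and either sated or fasted overnight for 16 to 18 hours. Mothers had litters of 8 pups aged 13 to 15 days. Tissue of 3 mice was pooled per group. Each of the 4 groups gave 1 ARC and 1 MPOA library, so there were 8 libraries and 1 library per group and region. The ARC was taken from 9 to 10 slices per group and the MPOA from 7 to 8, each slice 225 µm thick, and the tissue was dissociated with a protease. About 12000 cells were loaded per library, and viability was 67.5 to 82.3%. Whether the ARC and MPOA libraries of a group came from the same 3 mice, and on which days the pools were prepared, is not given in the sources used here.

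The deposited matrices hold raw UMI counts (unique molecular identifiers, 1 per captured RNA molecule) per gene and barcode, made by the authors with Cell Ranger 7.0.0, per the file headers. The chemistry was 10x Genomics version 3, per the labels, and the genome mm10, per the submitters' processing notes. The annotation release behind the counts, whether intron reads were counted and how barcodes were called cells are not given in the sources used here. Values were whole numbers, the library totals differed, and the lowest barcode total was 500 UMIs. Each matrix has 32285 genes, of which 78 rows share their symbol with another row and were told apart by Ensembl ID. The total count per library was 48632216, 39973586, 95787355 and 49539281 in the ARC and 65985784, 101423692, 86072136 and 64379746 in the MPOA, over 13544, 12433, 22646 and 11279 and 14257, 20857, 18280 and 15084 barcodes. Series of 4 values are given throughout in the order sated virgins, fasted virgins, sated mothers and fasted mothers.

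Barcodes with under 500 genes or under 1000 UMIs were left out (24.8, 22.6, 41.5 and 16.6% of ARC and 34.6, 38.8, 32.5 and 37.0% of MPOA barcodes). Barcodes with over 20% mitochondrial UMIs were also left out, which took 1, 0, 6 and 1 further barcodes in the ARC and 20, 502, 39 and 140 in the MPOA. Doublets were called in each library with Scrublet as built into scanpy 1.11.5 (expected rate 8%, automatic threshold) and removed. They made up 3.72, 3.93, 3.82 and 3.99% of the remaining ARC barcodes and 3.31, 4.92, 3.18 and 2.96% of the remaining MPOA barcodes. This left 9809, 9242, 12731 and 9035 ARC cells and 8999, 12043, 11921 and 9187 MPOA cells, with median UMI counts of 3692, 3232, 5360 and 4404 and 5256, 5692, 5040 and 4939.

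Cells of each region were clustered with leidenalg on a graph of shared neighbours (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1), and neurons were clustered again at resolution 2. The 16 gene lists, mitochondrial, ribosomal protein and haemoglobin genes and Xist were left out of the clustering features, so Agrp, Npy and Pomc did not place a cell. A cluster was named "X-like" from marker lists fixed before the data were examined. It needed at least 3 detected markers and a mean log2 ratio of its markers over the other clusters of at least 2 for classes or 1.5 for neuron types, and those 2 thresholds were set after the data were seen. The naming markers of AgRP-like neurons include Agrp and Npy, and those of POMC-like neurons Pomc and Cartpt. Neurons were the remaining clusters with at least 3 neuronal markers. The thresholds kept these neuron sub-clusters out of the type they scored highest for, with shares of neurons in parentheses: ARC sub-cluster 34, dopamine (1.51, 1.49, 1.53 and 1.54%), MPOA 1, Adcyap1/Bdnf preoptic (4.29, 3.16, 3.13 and 6.11%), MPOA 3, magnocellular (2.91, 5.67, 3.01 and 1.74%), MPOA 14, galanin preoptic (1.90, 2.51, 4.78 and 1.90%), MPOA 39, suprachiasmatic (0.866, 2.30, 0.770 and 0.611%), and MPOA 40, striatal-type (1.01, 0.484, 0.591 and 0.950%). Unnamed cells were 2.07, 0.941, 6.21 and 1.75% of ARC and 4.29, 6.98, 14.7 and 6.38% of MPOA cells. Clusters led by markers of a second class were 2.84, 5.56, 5.29 and 1.96% of ARC and 2.92, 2.37, 2.02 and 3.76% of MPOA cells for neurons led by other markers, and 0.306, 0.173, 0.275 and 0.133% and 2.56, 3.89, 2.95 and 1.38% for mixed cells, and these were not used. The names were rebuilt here from markers, so cells can be parted differently from the study's own names.

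Counts were summed per library and class and scaled by the class total to CPM. Cells are not replicates and each group has 1 library per region, so no test was run and no p-value is given. Sums have exact 95% Poisson intervals, ratios of sums exact binomial intervals and shares Clopper-Pearson intervals. These cover counting error only, not the spread between pools of mice, dissections or libraries. A log2 ratio adds 0.5 counts to each sum. A ratio against a count of 0 was computed against a floor of 3 counts and is written "at least", and no ratio is given where both groups were at or under that floor.

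Fasting was described by fasted against sated virgins and fasted against sated mothers. Lactation was described by mothers against virgins within sated and within fasted mice. Pairs of folds in parentheses are in that order. The 2 pairs of a factor share no library, whereas a fasting and a lactation pair do. Genes were summarised by a rule of size: at least 1.5-fold in the same direction in both pairs, among genes with at least 400 counts over the 4 libraries of the region and class. Its counts describe these libraries and are not calls. Beside each count over all neurons of a region stands the number of genes that met it in opposite directions and the number that 2 independent lists of the same lengths would share. On simulated counts with 100 genes changed 2-fold and 100 changed 3-fold, the rule recovered 99% and 98% of them for ARC fasting (13676 genes), 99% and 96% for ARC lactation (13685 genes), 100% and 94% for MPOA fasting (14123 genes) and 100% and 96% for MPOA lactation (14133 genes). In each case 0 unchanged genes met it, but these counts hold counting noise alone, not the spread between pools and libraries, so the 0 is no error rate of the rule. In the data 23, 32, 49 and 46 genes met it in opposite directions.

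The named genes follow a rule fixed before the data were examined. They are the 8 higher and 8 lower genes in neurons, and the 5 higher and 5 lower in AgRP-like neurons and in astrocyte-, oligodendrocyte-, microglia-, tanycyte- and endothelial-like cells, that met the size rule with the largest smaller-of-2 log2 ratio. Mitochondrial, ribosomal protein, haemoglobin, Gm and Rik genes and markers of other classes were left out of that ranking. From the gene lists each comparison is about, 2 to 4 members with at least 100 counts and the largest smaller-of-2 ratio are named, and Agrp, Npy, Pomc, Cartpt and Brs3 always. A few genes that the rule picks are not reported here. The 16 lists, also fixed in advance, were appetite peptides and receptors, parenting and MPOA signalling, reproductive neuropeptide axis, dopamine synthesis, prolactin and STAT5 signalling, immediate early genes, heat shock, endoplasmic reticulum chaperones, glucocorticoid response, fasting metabolism, sterol synthesis, thyroid hormone handling, interferon response, microglial activation, astrocyte reactivity, and glucose and lactate handling. The median log2 ratio of a list's members with at least 100 counts has its percentile among 10000 random lists of the same size matched on mean expression, as a description.

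RNA released by other cells gives UMIs in cells that do not express a gene. Beside a share of cells with a UMI stands the share in oligodendrocyte-like cells, and both also after thinning each cell to 2000 UMIs. Alternatives fixed in advance were TMM factors (edgeR 4.0.16), DESeq2 1.42.0 size factors, the mean of per-cell CPM, a filter of 1000 genes and 2000 UMIs, at most 10% mitochondrial UMIs, doublets kept, no genes left out of the clustering features, Leiden resolution 1 for neurons, subtraction of the CPM of oligodendrocyte-like cells, thinning, and for gene counts a minimum of 100 counts, no minimum, and a 2-fold rule. A fixed makeup of neuron types and leaving out sub-clusters with at least 80% of their cells from 1 library were added after the data were seen. In the fixed makeup each type was weighted by its part of the pooled counts, alike in the 4 libraries. The fixed makeup used the types and unnamed sub-clusters with at least 20 cells in each library, 28 of 34 in the ARC and 39 of 43 in the MPOA. A gene held mostly by a type left out is thus read there from the other neurons. Coordinates are those of GENCODE release M21 on GRCm38, the assembly that mm10 names, matched by Ensembl ID. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3.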

Results

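The series profiled single cells of the arcuate nucleus (ARC) and the medial preoptic area (MPOA) of female mice that differed in reproductive state and in feeding state, and its title names a hypothalamic circuit for feeding and parenting. There was 1 library per region for sated virgins, fasted virgins, sated lactating mothers and fasted lactating mothers, each from a pool of 3 mice, and series of 4 values follow that order. There are no replicates, so no difference here has a replicate check, and intervals are 95% and cover counting error only. Folds given in pairs are for virgins then mothers when fasted are compared with sated mice, and for sated then fasted mice when mothers are compared with virgins.

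After filtering, the ARC libraries held 9809, 9242, 12731 and 9035 cells with 43914500, 35930116, 84362132 and 45442272 UMIs, and the MPOA libraries 8999, 12043, 11921 and 9187 cells with 59419324, 88283170, 77334931 and 57465236 UMIs. Neurons were 60.6 (59.7 to 61.6), 55.3 (54.3 to 56.3), 51.5 (50.6 to 52.4) and 59.8 (58.8 to 60.8)% of ARC cells by exact Clopper-Pearson intervals, with a median of 5322.5, 4656.5, 8602 and 6346 UMIs. They were 53.9 (52.8 to 54.9), 54.9 (54.0 to 55.8), 46.8 (45.9 to 47.7) and 48.1 (47.1 to 49.1)% of MPOA cells, with a median of 8340.5, 9268, 8383 and 8168.5 UMIs. Among ARC cells, astrocyte-like cells were 9.07, 10.3, 11.9 and 10.2%, tanycyte-like cells (ependymal glia that line the third ventricle) 12.6, 12.5, 8.10 and 11.3% and oligodendrocyte-like cells 1.97, 4.37, 3.38 and 3.19%. Microglia-like cells were 2.35, 3.05, 2.63 and 2.50% and endothelial-like cells 1.53, 1.504, 2.54 and 1.75%. In the MPOA the astrocyte-like share was 13.8, 12.3, 12.2 and 13.9%, the oligodendrocyte-like share 9.40, 7.89, 8.01 and 10.99%, the microglia-like share 1.91, 2.27, 1.95 and 2.16% and the endothelial-like share 3.17, 2.06, 3.25 and 4.26%. Named ARC neuron types were AgRP-like neurons (694, 699, 725 and 765 cells), POMC-like neurons (367, 329, 481 and 418) and KNDy-like neurons, which hold kisspeptin, neurokinin B and dynorphin (375, 294, 367 and 307). The others were tuberoinfundibular dopamine-like neurons (161, 138, 153 and 186), GHRH-like neurons (269, 276, 271 and 341) and ventromedial hypothalamus-like neurons (390, 445, 725 and 349). Shares depend on each dissection, which 1 library per group cannot separate from the group.

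The first comparison asked how hunger neurons and their neighbours in the ARC differed between fasted and sated mice. In AgRP-like neurons, Agrp, which encodes the hunger peptide agouti-related peptide, was 3.38-fold (3.23 to 3.54) higher in fasted than in sated virgins and 1.15-fold (1.12 to 1.18) higher in fasted than in sated mothers. Its levels were 535 CPM (514 to 557) in sated virgins, 1808 CPM (1767 to 1849) in fasted virgins, 1349.9 CPM (1325 to 1375) in sated mothers and 1551 CPM (1519.7 to 1583) in fasted mothers. Npy, which encodes the appetite-stimulating neuropeptide Y, was 2.86-fold (2.78 to 2.93) and 1.47-fold (1.44 to 1.49) higher. Vgf, which encodes a precursor of secreted neuropeptides, differed most among the appetite genes, at 27.0, 1451, 93.5 and 1262 CPM, or 53.7-fold (44.9 to 64.8) and 13.5-fold (12.5 to 14.5) higher with fasting. In POMC-like neurons, Pomc, the precursor of the satiety peptide alpha-MSH, was 1.84-fold (1.73 to 1.96) lower in fasted virgins (843 against 1552 CPM) and 1.80-fold (1.71 to 1.90) lower in fasted mothers (579 against 1044 CPM).

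On mm10, the genes lie at these places: Agrp (ENSMUSG00000005705, chromosome 8, 105566698 to 105637393, minus strand), Npy (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507, plus strand), Vgf (ENSMUSG00000037428, chromosome 5, 137026392 to 137033351, plus strand), Pomc (ENSMUSG00000020660, chromosome 12, 3954951 to 3960642, plus strand) and Cartpt (ENSMUSG00000021647, chromosome 13, 99898489 to 99901091, minus strand). An Agrp UMI was seen in 86.5, 95.9, 98.8 and 98.8% of AgRP-like neurons and in 3.11, 6.19, 9.07 and 9.72% of oligodendrocyte-like cells, which should lack it. Their median depths were 6613, 5406, 11078 and 7781 and 2434, 1994, 3201 and 2388 UMIs. With each cell thinned to 2000 UMIs the shares were 59.2, 89.0, 84.5 and 87.0% and 3.03, 5.50, 5.74 and 6.38%, with 17, 24, 9 and 6 and 61, 204, 64 and 100 shallower cells left out. Different sub-clusters held the AgRP-like neurons of fasted and sated mice: sub-clusters 5 (8, 389, 34 and 504 cells) and 24 (1, 259, 4 and 224) held most of those of fasted mice, and sub-clusters 17 (279, 13, 329 and 19), 28 (236, 35, 155 and 16) and 31 (170, 3, 203 and 2) most of those of sated mice. KNDy-like neurons likewise lay mostly in sub-cluster 20 in sated mice and in sub-cluster 25 in fasted mice.

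**Figure D1:**
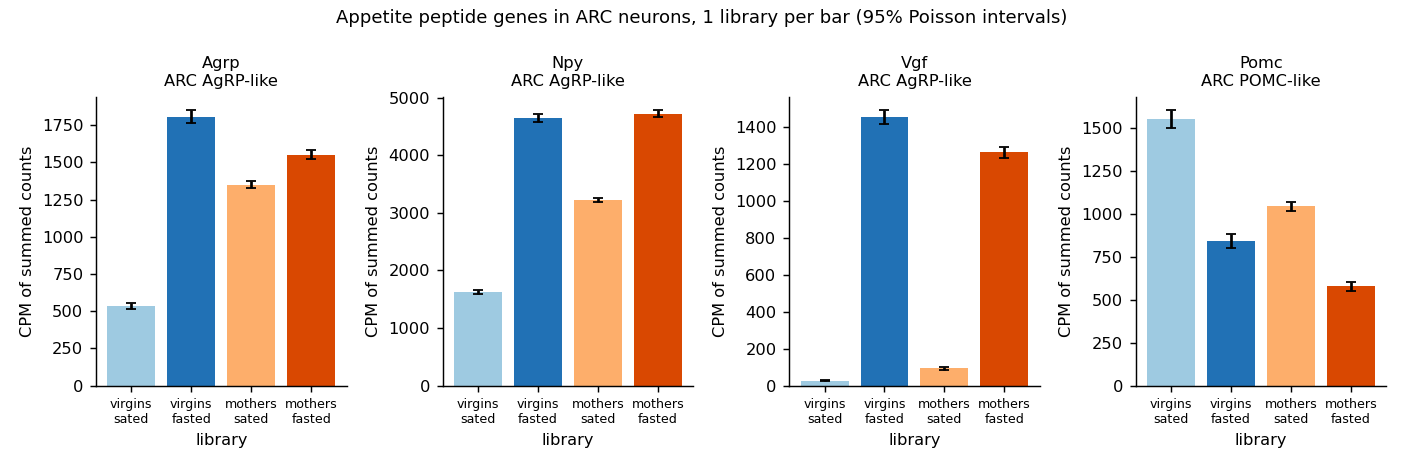
CPM of Agrp, Npy and Vgf in AgRP-like ARC neurons and of Pomc in POMC-like ARC neurons; each bar is 1 library (sated virgins, fasted virgins, sated mothers, fasted mothers) and error bars are 95% Poisson intervals of the summed counts. Vgf stood at 1451 and 1262 CPM in the fasted libraries against 27.0 and 93.5 in the sated ones, and Agrp at 1349.9 CPM in sated mothers lay between sated and fasted virgins.

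The AgRP-like neurons differed with fasting in many more genes than these. By the size rule, 953 of 8219 genes were at least 1.5-fold apart in the same direction in both pairs, 458 higher and 495 lower, against 4 in opposite directions and 73.7 higher and 83.4 lower for independent lists. The highest ranked were Slco1a1, an organic anion transporter, at 77.6-fold (26.2 to 379) and 66.9-fold (33.6 to 156), Cdkn1a, which encodes the cell cycle inhibitor p21 (98.0- and 46.5-fold), the neuromedin B receptor gene Nmbr (68.7- and 14.8-fold), Vgf, and Hhip, which encodes a hedgehog-binding protein (99.2- and 13.6-fold). The lower ones were Rgs6, a regulator of G protein signalling (10.7- and 7.34-fold), the circadian clock genes Per3 (9.32- and 7.23-fold), Bhlhe40 (25.4- and 5.90-fold) and Dbp (6.13- and 4.79-fold), and Necab1, a calcium-binding protein gene (4.69- and 4.57-fold). The lowest lower bound of these 10 genes' ratio intervals was 3.30 (Necab1 in mothers). Receptors for hormones of energy state also differed, with the ghrelin receptor gene Ghsr (4.22- and 3.38-fold) and the leptin receptor gene Lepr (5.403- and 3.20-fold) higher and Npy2r, an autoreceptor for neuropeptide Y, lower (4.23- and 3.02-fold). The prohormone convertase gene Pcsk1 was 2.61- and 3.17-fold higher.

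**Figure D2:**
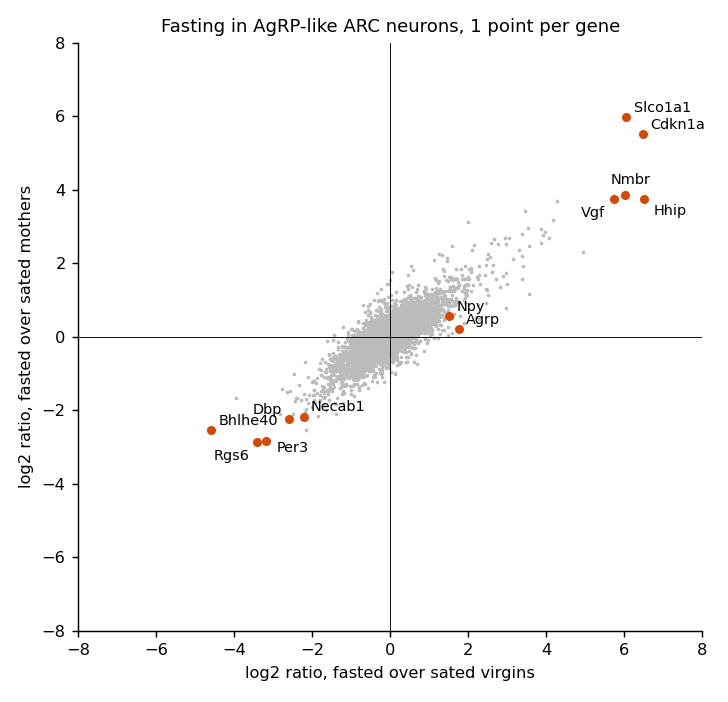
Log2 ratio of fasted to sated CPM in AgRP-like ARC neurons, virgins on the x axis and mothers on the y axis; each point is a gene with at least 400 counts over the 4 libraries, and named genes are labelled. Vgf, Cdkn1a and Slco1a1 lie far to the upper right, Per3 and Dbp to the lower left, and 4 genes met 1.5-fold in opposite directions.

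The gene lists divided in these cells. Of the endoplasmic reticulum chaperone list, whose products fold secreted proteins, 12 of 18 measured members were at least 1.5-fold higher in both pairs (median log2 ratio 0.91 and 0.83), among them Hspa5 (2.35- and 2.77-fold), Hyou1 (2.33- and 2.07-fold) and Pdia6 (2.96- and 2.05-fold). Of the glucocorticoid response list, 8 of 12 were higher (median 1.32 and 0.91), with Errfi1 (3.34- and 2.49-fold), Mt2 (5.61- and 2.44-fold) and Fkbp5 (3.61- and 2.39-fold) after Cdkn1a. Of the sterol synthesis list, 7 of 19 were lower (median -0.75 and -0.36), among them Nsdhl (3.798- and 2.17-fold) and Stard4 (1.93- and 2.54-fold). Of the fasting metabolism list, 2 of 7 were higher, Foxo1 (2.81- and 1.78-fold) and Irs2 (1.66- and 1.98-fold), both of the insulin signalling pathway. The appetite list had 6 members higher and 2 lower of 17 (median 0.83 and 0.44). From the parenting list, the neurotensin gene Nts was 18.6- and 14.3-fold higher, from 1.11 and 1.58 CPM when sated. Immediate early genes parted the pairs, with medians of -0.07 and 1.25.

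Vgf parted the other ARC neuron types. It was 5.62-fold (4.70 to 6.76) and 4.07-fold (3.52 to 4.73) lower with fasting in POMC-like neurons and 6.34-fold (4.49 to 9.21) and 5.10-fold (3.75 to 7.09) lower in KNDy-like neurons, but 1.95-fold (1.70 to 2.24) and 5.46-fold (4.87 to 6.13) higher in dopamine-like neurons, the direction of AgRP-like neurons. In POMC-like neurons Cartpt, which encodes a satiety peptide, was 2.03- and 2.38-fold lower, and 111 of 6113 genes met the size rule, 42 higher and 69 lower. The endoplasmic reticulum chaperones there had medians of -0.50 and -0.15, and immediate early genes -1.34 and -0.58. Npy was 3.18- and 2.56-fold higher in POMC-like neurons, at 14.8, 47.1, 19.7 and 50.4 CPM, far below its level in AgRP-like neurons and in the same order across the 4 libraries. In KNDy-like neurons the progesterone receptor gene Pgr (3.32- and 5.80-fold) and Tac2, which encodes neurokinin B (1.52- and 1.51-fold), were lower with fasting. Tanycyte markers in KNDy-like neurons were higher with fasting in both pairs, at 127, 179, 84.6 and 164 CPM, and in dopamine-like neurons lower, at 265, 179, 219.5 and 143. Oligodendrocyte markers in POMC-like neurons were at 51.4, 68.4, 47.5 and 61.1 CPM. The glucocorticoid response list had medians above 0 in each of these types, 1.07 and 1.06 in POMC-like, 1.27 and 0.18 in KNDy-like, 1.83 and 0.56 in dopamine-like, 1.02 and 0.54 in GHRH-like and 0.79 and 0.20 in ventromedial hypothalamus-like neurons.

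Over all ARC neurons, 286 of 13671 genes met the size rule with fasting, 175 higher and 111 lower. Another 23 met 1.5-fold in opposite directions, and independent lists would share 16.7 higher and 12.4 lower genes. Among the highest ranked were Slco1a1 (57.4- and 85.5-fold), of whose neuronal counts 96.5% lay in AgRP-like neurons, Cdkn1a (9.06- and 10.1-fold), the chemokine gene Ccl17 (10.6- and 7.79-fold), the hyaluronan receptor gene Layn (13.8- and 7.05-fold), the thrombospondin gene Thbs1 (5.08- and 4.72-fold), Hhip (15.1- and 4.57-fold) and Nmbr (14.2- and 4.39-fold). The 8 lowest were the guanylate-binding protein gene Gbp6 (9.15- and 4.31-fold), the nuclear receptor gene Nr4a2 (3.96- and 4.30-fold), the prokineticin gene Prok2 (3.53- and 5.06-fold), the inhibin subunit gene Inhbb (5.66- and 3.40-fold), and Rgs6 (2.64- and 2.96-fold), B4galnt3 (2.21- and 2.48-fold), Plch1 (2.20- and 2.14-fold) and Rdm1 (2.14- and 2.43-fold). With cells thinned to 2000 UMIs, 151 genes met the rule, 124 of them among the 286, and with the CPM of oligodendrocyte-like cells subtracted 2267 did. Markers of other cells in neurons were at 280.3, 293, 282 and 259 CPM for astrocytes and 68.0, 78.0, 56.1 and 61.3 for oligodendrocytes.

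The gene lists divided as follows in ARC neurons with fasting, each median log2 ratio followed by its percentiles among random lists. The glucocorticoid response list stood at 1.12 and 0.96 (percentiles 100 and 100), with 8 of 14 members at least 1.5-fold higher in both pairs, led by Cdkn1a and Fkbp5 (3.37- and 2.50-fold) and Zbtb16 (3.14- and 2.49-fold). The appetite list stood at 0.09 and 0.11 (96.0 and 92.0), with 5 of 19 higher, among them Ghsr (2.80- and 3.53-fold), Vgf (2.52- and 3.47-fold) and Lepr (3.15- and 2.50-fold), and 4 lower, among them Npy2r (2.19- and 2.12-fold) and Cartpt (2.18- and 1.89-fold). The parenting list stood at -0.31 and -0.26 (0 and 0.0300), with 4 of 18 lower, such as the oxytocin receptor gene Oxtr (2.02- and 1.96-fold) and Pgr (1.70- and 1.76-fold) and Adcyap1 (1.62- and 2.06-fold), and 1 higher, Nts (2.10- and 4.76-fold). The reproductive axis stood at -0.41 and -0.60 (0.01 and 0; 3 of 8 lower), fasting metabolism at 0.32 and 0.16 (99.98 and 81.9), with Txnip (2.82- and 2.44-fold) and Foxo1 (1.99- and 1.69-fold) higher, and prolactin and STAT5 signalling at -0.22 and -0.17 (1.14 and 1.27). Heat shock genes stood at -0.31 and -0.26 (0.0400 and 0.130) and interferon response genes at -0.55 and -0.24 (0.610 and 2.02).

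Virgins and mothers parted in 2 lists of ARC neurons, dopamine synthesis at -0.45 and 0.35 (0 and 99.8) and immediate early genes at -0.33 and 0.23 (0 and 97.5). The remaining lists had these medians: endoplasmic reticulum chaperones 0.06 and 0.16 (87.9 and 97.0), sterol synthesis -0.31 and -0.06 (0 and 5.33) and thyroid hormone handling 0.09 and -0.02 (87.6 and 29.4). Glucose and lactate handling stood at -0.01 and 0.10 (40.4 and 64.0), microglial activation 0.05 and 0.06 (77.2 and 45.8) and astrocyte reactivity 0.02 and -0.18 (64.7 and 9.03). With each neuron type weighted alike in the 4 libraries, the highest and lowest ranked genes named above kept the rule.

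In glial and vascular cells of the ARC, Fkbp5, a co-chaperone of the glucocorticoid receptor (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527, minus strand), was 8.70- and 5.58-fold higher with fasting in astrocyte-like, 16.2- and 4.56-fold in oligodendrocyte-like, 9.53- and 6.47-fold in microglia-like, 6.25- and 3.89-fold in tanycyte-like and 18.4- and 9.16-fold in endothelial-like cells. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand) was 99.5-fold (38.7 to 366) and 65.2-fold (36.9 to 127) higher in oligodendrocyte-like cells, 11.7- and 6.15-fold in astrocyte-like cells and 6.47- and 1.79-fold in endothelial-like cells. The list's members at least 1.5-fold higher in both pairs were 10 of 13 in oligodendrocyte-like, 9 of 12 in tanycyte-like, 8 of 13 in astrocyte-like, 6 of 12 in microglia-like and 5 of 10 in endothelial-like cells.

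In ARC astrocyte-like cells, 151 genes met the size rule (94 higher, 57 lower). After Cdkn1a and Fkbp5 the higher genes were Txnip, a thioredoxin-binding protein gene (8.61- and 3.38-fold), the thyroid hormone target Hr (4.88- and 3.36-fold) and Kcnt1 (2.84- and 3.14-fold). The lower genes were Tubb2b (2.62- and 2.14-fold), Slc13a3 (3.18- and 2.13-fold), Nav3 (2.87- and 2.11-fold), Ndufc1 (2.18- and 2.05-fold) and Shroom3 (1.98- and 2.17-fold). In oligodendrocyte-like cells 132 met it (80 and 52), with Zfand4 (18.4- and 9.46-fold), Itgad (19.6- and 6.27-fold), Tma16 (9.02- and 6.19-fold) and Arrdc2 (7.202- and 5.06-fold) higher after Cdkn1a. Their lower genes were Eml1 (3.29- and 2.84-fold), Npas3 (2.86- and 2.74-fold), Fabp5 (7.48- and 2.46-fold), Gng11 (2.41- and 2.45-fold) and Ugt8a (2.20- and 2.31-fold). Summed neuron markers were also higher with fasting in these cells, at 414, 597, 487 and 668 CPM, as were microglia markers, at 52.5, 78.7, 66.7 and 94.9. In microglia-like cells 68 met it (34 and 34), with Slc43a2 (2.55- and 2.34-fold), Ucp2 (2.58- and 2.23-fold), Rassf2 (2.18- and 2.28-fold) and Ppp1r21 (3.28- and 2.11-fold) higher after Fkbp5. The chemokine gene Ccl12 (5.48- and 2.42-fold), the interleukin gene Il1a (3.37- and 2.13-fold) and Nav3 (2.89- and 2.36-fold), Kcnma1 (2.52- and 2.23-fold) and Hdac9 (2.56- and 2.08-fold) were lower. Astrocyte markers in microglia-like cells were at 919.8, 1158, 871 and 1180.3 CPM and oligodendrocyte markers at 157, 229.8, 156 and 191.

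In tanycyte-like cells 193 genes met the rule (107 higher, 86 lower). The higher were Setdb2 (12.6- and 9.98-fold), Pnpla7 (7.06- and 5.49-fold), Wfikkn2 (37.2- and 4.68-fold), Kcnt1 (4.42- and 4.40-fold) and Txnip (4.16- and 4.25-fold). The lower were the cystine transporter gene Slc7a11 (3.63- and 3.00-fold) and Cfap299 (2.51- and 2.41-fold), Igfbp5 (5.10- and 2.14-fold), Fabp5 (2.42- and 2.14-fold) and Ttc29 (3.10- and 2.14-fold). Astrocyte markers were at 4144, 5387, 4432 and 5733 CPM in these cells. Dio2, whose product activates thyroid hormone, was 2.90- and 1.71-fold higher there. In endothelial-like cells 46 met the rule in the same direction and 36 in opposite directions. Neuron markers in these cells also parted the pairs, at 1530, 637, 788 and 1366 CPM. The higher genes were Net1 (4.59- and 4.40-fold), Plat (5.01- and 3.19-fold), Ranbp9 (4.80- and 2.30-fold), Mal (4.98- and 2.17-fold) and Xdh (5.12- and 2.15-fold). There Slc6a6 (2.26- and 2.49-fold), Podxl (1.77- and 1.92-fold), Pltp (1.69- and 1.96-fold), Etl4 (1.68- and 1.68-fold) and Oxr1 (1.60- and 1.80-fold) were lower.

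In the MPOA, which holds neurons for parental behaviour, fewer neuronal genes differed with fasting. Over all MPOA neurons 70 of 14130 genes met the rule, 46 higher and 24 lower, against 49 in opposite directions and 3.34 and 6.39 for independent lists. Cdkn1a was 3.05-fold (2.65 to 3.53) and 4.74-fold (4.04 to 5.598) higher. The other higher genes were the chromatin protein gene Hmgb2 (2.19- and 2.41-fold), Zbtb16, which encodes a glucocorticoid-induced zinc finger protein (2.73- and 2.04-fold), and Hr (2.08- and 1.96-fold), Klra2 (1.95- and 1.98-fold), Slc9b1 (1.93- and 2.21-fold) and Sowaha (1.94- and 1.88-fold). Vmn2r56 (2.61- and 4.79-fold) belongs to a family of near-identical vomeronasal receptors, so its identity is uncertain. The lower genes were the oxytocin gene Oxt (2.02- and 3.84-fold), of whose neuronal counts 89.9% lay in the magnocellular-like sub-cluster of 38, 52, 27 and 11 cells, and Creb3l1 (2.49- and 1.98-fold), Mafa (2.15- and 1.89-fold), Tnxb (1.87- and 2.12-fold), Vinac1 (2.17- and 1.84-fold), Sox14 (2.39- and 1.77-fold) and Ccdc158 (1.83- and 1.68-fold). The milk protein gene Csn1s1 was 3.33-fold (2.58 to 4.34) lower in fasted than sated mothers. It is counted among the lower genes only through the 0.5 counts added to each sum, since virgins had 1 and 0 counts, too few for a fold. With each neuron type weighted alike in the 4 libraries, Csn1s1, Creb3l1, Mafa, Vinac1 and Sox14 no longer met the rule. The log2 ratio of Csn1s1 in mothers then went from -1.73 to -0.54, and that of Oxt in virgins from -1.02 to -2.09. That weighting leaves out the magnocellular-like sub-cluster, which had too few cells in fasted mothers, so the Oxt value covers the other neurons only. Within the magnocellular-like sub-cluster Oxt stood at 81517, 44169, 94631 and 49642 CPM. With thinned cells 20 genes met it, 14 of them among the 70, and 1415 with oligodendrocyte-like CPM subtracted.

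The receptor gene Brs3 (ENSMUSG00000031130, chromosome X, 57043074 to 57048758, plus strand), found on feeding-related hypothalamic neurons, stood at 13.2 CPM (12.2 to 14.3) in MPOA neurons of sated virgins and 13.0 CPM (12.1 to 13.8) in fasted virgins, a ratio of 0.981 (0.883 to 1.09), so no difference was detectable at this depth. In mothers it was 1.39-fold (1.22 to 1.58) higher when fasted (11.6 against 8.38 CPM). This difference was not alike across neurons. Sub-cluster 1 stood at 93.9 CPM in fasted against 28.7 in sated mothers (233 and 47 counts). Sub-cluster 14 stood at 30.6 against 36.9 CPM and sub-cluster 19 at 39.0 against 33.6. In virgins, sub-clusters 1, 14 and 19 stood at 70.9, 102 and 68.2 CPM when fasted against 65.7, 162 and 70.9 when sated. A Brs3 UMI was seen in 6.54, 6.95, 5.37 and 5.45% of neurons and in 0.355, 0.211, 0.628 and 0.0990% of oligodendrocyte-like cells (median depths 8340.5, 9268, 8383 and 8168.5 and 4243.5, 4145.5, 4512 and 4035.5 UMIs). Thinned to 2000 UMIs, the shares were 2.53, 2.42, 1.69 and 2.09% and 0.129, 0.228, 0.337 and 0.106%, with 34, 39, 11 and 19 and 72, 72, 65 and 69 cells left out.

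Of the glucocorticoid response list, 5 of 14 members were at least 1.5-fold higher in both pairs of MPOA neurons (median 0.92 and 0.70, percentiles 100 and 100), among them Fkbp5 (2.35- and 1.83-fold) and Sult1a1 (2.38- and 2.07-fold). With oligodendrocyte-like CPM subtracted the median in virgins turned to -0.63. Txnip was 4.10- and 2.37-fold higher and Foxo3 1.17- and 1.13-fold (fasting metabolism, median 0.11 and 0.09). The appetite list had 0 members higher and 0 lower of 19 (median -0.02 and 0.04), the largest being Npy5r (1.31- and 1.27-fold lower) and the GLP-1 receptor gene Glp1r (1.24- and 1.42-fold higher). The parenting list had 1 of 20 lower (median -0.07 and -0.07), Oxt, with Oxtr next (1.22- and 1.64-fold). MPOA neurons held 14.8, 11.2, 15.7 and 18.4 CPM of Agrp, 7.50, 3.05, 3.25 and 10.1 of Npy, 7.05, 8.04, 8.16 and 6.59 of Pomc and 57.0, 55.2, 103 and 61.8 of Cartpt. Across 13447 genes, the log2 ratios of ARC and MPOA neurons correlated with r = 0.486 for fasting in virgins and 0.612 in mothers. Genes are not independent replicates, and these are from 24 such correlations computed over 6 classes. Between the virgin and mother fasting pairs, r was 0.0127 across 14130 genes in MPOA neurons and 0.490 across 13671 genes in ARC neurons. The fasting ratios of MPOA neurons were thus not shared across genes between virgins and mothers.

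Oligodendrocyte-like cells had the largest number of genes past the size rule among the MPOA classes described, with 279 of 6175 genes meeting the rule, 196 higher and 83 lower. The number of genes compared differed between classes, so these counts do not rank them. It was 91 of 1486 in endothelial-like cells, a larger share, 96 of 6702 in astrocyte-like and 49 of 1642 in microglia-like cells. Different clusters held them in sated mice (cluster 4) and fasted mice (cluster 5). Of the glucocorticoid response list, 13 of 14 members were higher (median 2.67 and 1.53), Cdkn1a by 302-fold (173 to 585) and 58.1-fold (43.3 to 79.8), followed by Ddit4 (6.65- and 6.20-fold), Plin4 (31.1- and 4.73-fold) and Fkbp5 (17.6- and 4.31-fold). The fasting gene Pdk4, which encodes an inhibitor of pyruvate use, was 12.1- and 4.92-fold higher. Other higher genes were Tspan4, at 111-fold (37.7 to 541) and 15.2-fold (7.13 to 38.9), and Sh2b2 (16.7- and 12.6-fold), Itgad (26.5- and 11.9-fold) and Zfand4 (15.5- and 8.19-fold). The lower genes were Ugt8a, an enzyme of myelin lipid synthesis (2.27- and 2.24-fold), and Bfsp2 (4.35- and 4.83-fold), Rapgef5 (2.33- and 2.82-fold) and Slc22a23 (2.27- and 2.43-fold). Across genes, ARC and MPOA oligodendrocyte-like cells correlated with r = 0.858 in virgins and 0.827 in mothers.

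**Figure D3:**
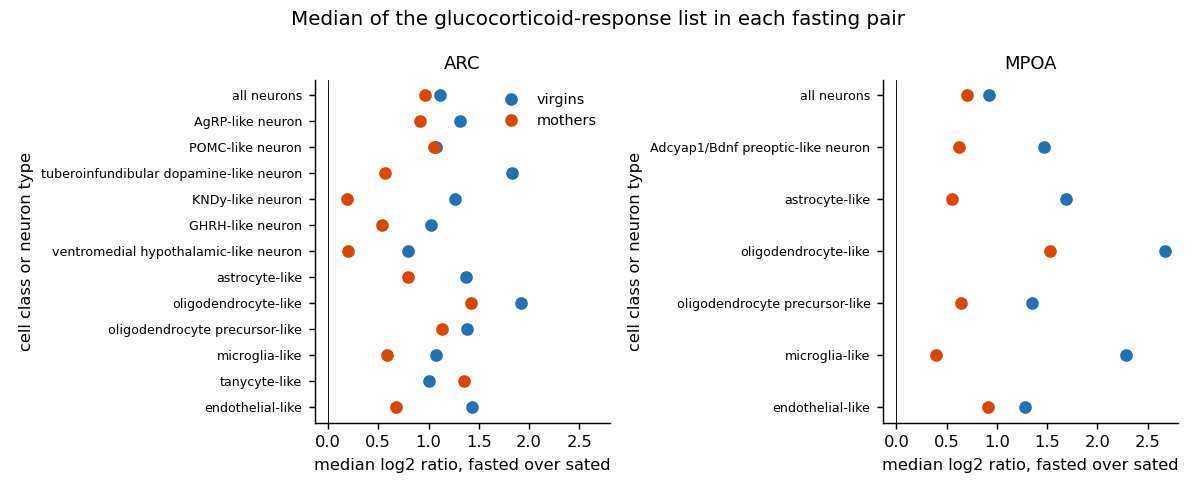
Median log2 ratio of fasted to sated mice over the glucocorticoid response list, by cell class and neuron type, in the ARC and in the MPOA; blue points are virgins and orange points mothers, 1 pair of libraries each, with no error bars. Within virgins and within mothers the highest points are oligodendrocyte-like MPOA cells, at 2.67 and 1.53, and ARC neurons lie at 1.12 and 0.96.

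In MPOA astrocyte-like cells 96 genes met the rule, with Cdkn1a (11.4- and 9.35-fold), Fkbp5 (18.3- and 4.93-fold), Hr (7.31- and 2.94-fold), Slc24a4 (4.66- and 2.43-fold) and Mycl (2.78- and 2.36-fold) higher. The lower ones were Rhcg (2.89- and 3.44-fold), Grm5 (2.17- and 2.14-fold), Pipox (2.66- and 2.00-fold), Slc13a3 (3.52- and 1.92-fold) and Adra2a (2.05- and 1.91-fold). In microglia-like cells 49 met it, 41 higher and 8 lower. The chemokine gene Ccl3 was 10.5-fold (7.57 to 15.1) and 6.08-fold (4.63 to 8.08) higher. Its relative Ccl4 (3.58- and 3.64-fold) was higher with Fkbp5 (10.5- and 5.03-fold), Rgs1 (8.48- and 2.80-fold) and Lifr (2.28- and 2.15-fold). Olfml3 (2.99- and 1.76-fold) was lower with Rbfox1 (2.24- and 3.70-fold), Kcnma1 (4.46- and 2.00-fold), Lrp1b (2.24- and 1.86-fold) and Lingo2 (1.77- and 7.11-fold), which neurons also express. Cdkn1a was not among the higher genes of microglia-like cells, at 54.3, 50.1, 33.8 and 35.2 CPM. In endothelial-like cells 82 genes were higher and 9 lower, with Ccn2 (8.21- and 4.43-fold), Trp53inp1 (4.41- and 4.87-fold), Plat (3.88- and 3.798-fold), Cdkn1a (3.24- and 3.03-fold) and Cdc42ep3 (3.06- and 2.87-fold) higher. The chemokine gene Cxcl12 (1.88- and 1.86-fold), the interferon-induced gene Ifitm3 (3.04- and 1.67-fold) and Sgpp2 (2.69- and 2.08-fold), Vwa1 (2.04- and 1.74-fold) and Bsg (2.34- and 1.60-fold) were lower. Oligodendrocyte markers were also higher with fasting in endothelial-like cells, at 341, 486, 360.0 and 474 CPM. Astrocyte markers in microglia-like cells were at 867, 1131, 1004 and 1182 CPM and neuron markers in oligodendrocyte-like cells at 447, 639, 741 and 789. In microglia-like cells the neuron markers were lower with fasting in both pairs, at 659, 567, 1027 and 697 CPM.

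**Figure D4:**
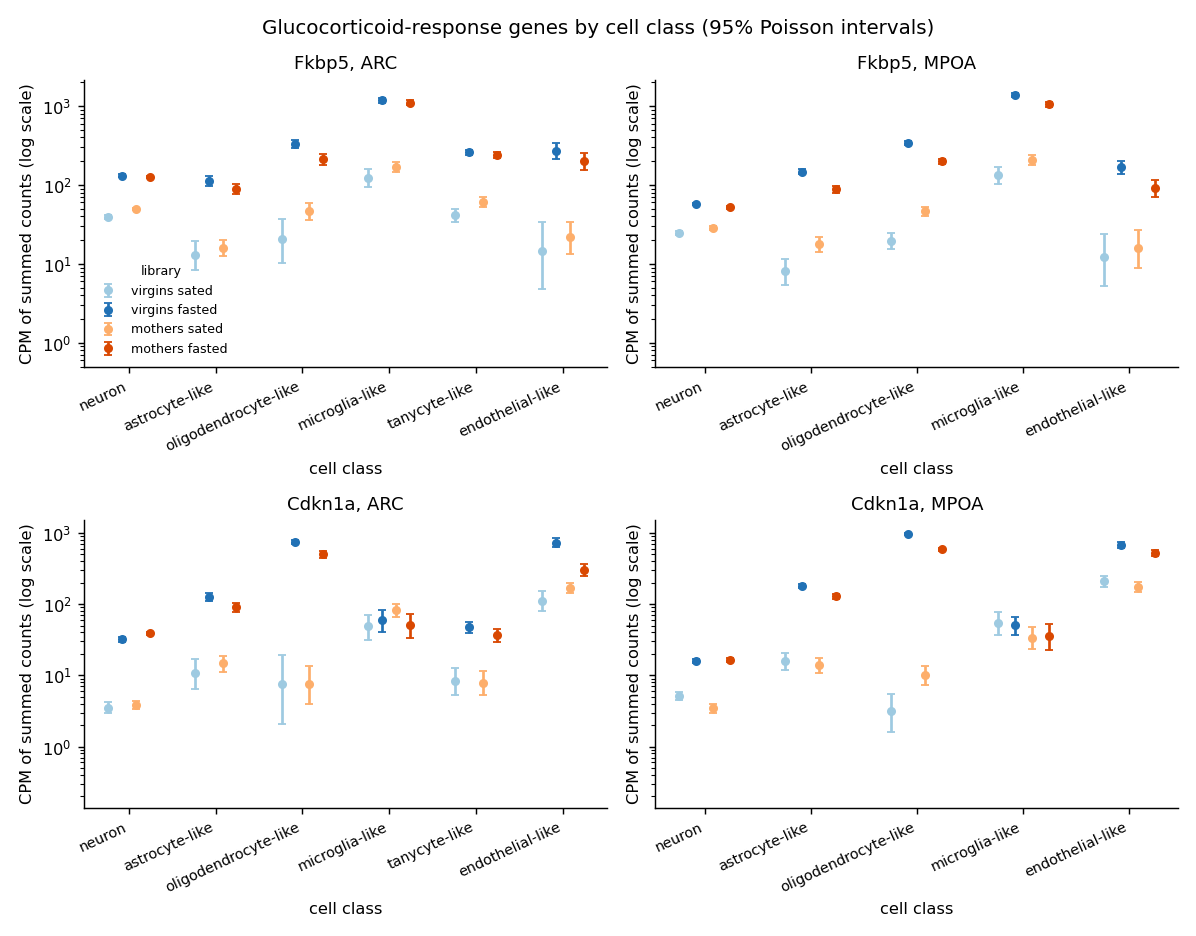
CPM of Fkbp5 and Cdkn1a by cell class in the ARC and the MPOA on a log axis, 1 point per library with 95% Poisson intervals. Cdkn1a in oligodendrocyte-like MPOA cells stood at 949 and 583 CPM in fasted virgins and mothers against 3.14 and 10.0 in sated ones.

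The next comparison asked how lactating mothers differed from virgins in the ARC. Agrp in AgRP-like neurons was 2.52-fold (2.41 to 2.64) higher in sated mothers than in sated virgins and 1.17-fold (1.13 to 1.20) lower in fasted mothers than in fasted virgins. Npy was 1.98-fold (1.93 to 2.03) higher in sated mothers, and in fasted mice its ratio of 1.02 (0.998 to 1.04) was not distinguishable from no difference. In POMC-like neurons Pomc was 1.49- and 1.45-fold lower in mothers, Cartpt 1.498- and 1.75-fold, and the dynorphin gene Pdyn 2.64- and 3.51-fold. In dopamine-like neurons, which restrain prolactin release, Penk, which encodes the enkephalin precursor (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819, minus strand), stood at 50.6, 93.3, 619 and 781 CPM, 12.2-fold (9.25 to 16.5) and 8.37-fold (6.62 to 10.7) higher in mothers.

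These dopamine-like neurons also held more Nts (5.32- and 6.32-fold), Tac2 (4.06- and 7.69-fold), Ghsr (5.07- and 3.65-fold) and Slc18a2, the vesicular monoamine transporter gene (2.04- and 1.58-fold), and less Cartpt (3.22- and 3.92-fold). Their tyrosine hydroxylase gene Th stood at 501, 384, 465 and 808 CPM. A Penk UMI was seen in 20.5, 25.4, 81.0 and 77.4% of them and in 0.518, 0.495, 2.09 and 1.39% of oligodendrocyte-like cells (median depths 5987, 5411.5, 9661 and 7822 and 2434, 1994, 3201 and 2388 UMIs). Thinned to 2000 UMIs, the shares were 11.9, 10.9, 49.7 and 55.4% and 0.758, 0.500, 1.37 and 1.06%, with 1, 1, 2 and 0 and 61, 204, 64 and 100 cells left out. In KNDy-like neurons, Cish, a target of prolactin signalling, was 4.35- and 2.11-fold higher in mothers.

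Over all ARC neurons 53 of 13671 genes met the size rule with lactation, 26 higher and 27 lower, against 32 in opposite directions and 1.77 and 6.50 for independent lists. The higher were the forkhead gene Foxq1 (6.75- and 3.59-fold), the matricellular protein gene Ccn3 (2.63- and 2.68-fold), the gonadotropin-releasing hormone gene Gnrh1 (2.55- and 4.29-fold), Pamr1 (2.37- and 2.22-fold), the vasopressin gene Avp (3.90- and 2.10-fold), Adgrg6 (3.28- and 2.09-fold), Penk (2.06- and 4.53-fold) and the histamine synthesis gene Hdc (1.97- and 2.33-fold). The lower were the neprilysin gene Mme (2.53- and 3.17-fold), the glutamine transporter gene Slc38a3 (2.13- and 3.74-fold) and Smoc2 (3.19- and 1.93-fold), Acss3 (2.05- and 1.74-fold), Col2a1 (1.72- and 1.84-fold), Col24a1 (2.12- and 1.63-fold), Lpar1 (1.78- and 1.60-fold) and Tnxb (1.80- and 1.59-fold). Of Avp counts 89.0% lay in magnocellular-like neurons, which numbered 13, 59, 61 and 78 cells. With each neuron type weighted alike in the 4 libraries the log2 ratios of Gnrh1 turned to -0.18 and -0.85, and the other 15 kept the rule. That weighting leaves out the magnocellular-like neurons, which had too few cells in sated virgins, so for Avp it covers the other neurons only. Within magnocellular-like neurons Avp stood at 29281, 12061, 32766 and 19071 CPM, and these cells were 0.219, 1.15, 0.930 and 1.44% of neurons. In sated mice their Avp level was thus near alike while their share was higher in mothers. The Avp fold of all neurons in sated mice therefore goes largely with their number, of which sated virgins had 13 cells. In fasted mice both the level and the share were higher in mothers, and the part of each stays open. Thinned cells gave 21 genes, 8 of them among the 53, and subtraction of oligodendrocyte-like CPM 1751.

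By list, the parenting genes had 4 of 18 members higher in mothers in both pairs (median 0.09 and 0.18, percentiles 99.5 and 99.9): Avp, Penk, Nts (1.65- and 3.72-fold) and the thyrotropin-releasing hormone gene Trh (2.51- and 1.68-fold). Prolactin and STAT5 signalling had 2 of 12 higher, Cish (1.89- and 1.90-fold) and Socs2 (2.14- and 1.66-fold), with medians of -0.05 and -0.02. Dopamine synthesis had 2 of 8 higher, Penk and Slc18a2 (1.51- and 1.81-fold), with medians of -0.12 and 0.59, and the reproductive axis 1 of 8, Gnrh1. Pdyn was 1.24- and 1.37-fold lower. No appetite gene of 19 met 1.5-fold in both pairs (median -0.02 and -0.09), the largest being Npy2r (1.38- and 1.43-fold) and Ghsr (1.31- and 1.66-fold). In AgRP-like neurons 48 genes met the rule, with Foxq1 (3.89- and 3.17-fold), the synaptic vesicle gene Sv2b (3.53- and 2.13-fold) and Oxt (2.75- and 1.99-fold), Cyyr1 (4.48- and 1.98-fold) and Nptx2 (1.96- and 2.46-fold) higher. The somatostatin gene Sst (1.80- and 2.24-fold), the immediate early genes Btg2 (2.69- and 2.05-fold) and Egr1 (3.75- and 1.86-fold), and Cntnap5b (2.73- and 2.24-fold) and Epha5 (1.94- and 2.19-fold) were lower. Among ARC glia few genes met it, and in most classes more went in opposite directions. The same-direction and opposite numbers were 8 and 11 in astrocyte-like, 2 and 13 in oligodendrocyte-like, 3 and 3 in microglia-like and 4 and 14 in tanycyte-like cells. The astrocyte filament gene Gfap (1.68- and 1.61-fold) and Ctnna3 (1.92- and 1.85-fold), Rimbp2 (1.78- and 2.11-fold) and Brinp2 (1.53- and 1.71-fold) were lower in astrocyte-like cells. The lysozyme gene Lyz2 (1.77- and 1.88-fold) was lower in microglia-like cells. Oxt and Avp were higher in mothers in several ARC types at once, for example 20.2, 23.8, 55.5 and 47.3 CPM of Oxt in AgRP-like and 38.3, 25.2, 75.6 and 51.6 in POMC-like neurons.

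The last comparison asked how mothers differed from virgins in the MPOA. The amylin gene Iapp (ENSMUSG00000041681, chromosome 6, 142298423 to 142303961, plus strand) stood at 0.0449, 0.0290, 16.9 and 3.31 CPM in MPOA neurons, 375-fold (104 to 3103) and 114-fold (31.0 to 951) higher in mothers. The milk protein gene Csn1s1 (ENSMUSG00000070702, chromosome 5, 87666208 to 87682578, plus strand) stood at 0.0225, 0, 6.04 and 1.81 CPM, 269-fold (47.9 to 10643) higher in sated mothers and at least 41.7-fold higher in fasted mothers. The Csn1s1 folds have unlike bases, 1 count in sated virgins and the floor of 3 counts in fasted virgins. Those of Iapp rest on 2 neurons with a UMI in each virgin library. The sizes of these folds are thus uncertain. The follistatin gene Fst (11.7- and 3.61-fold), the melanin-concentrating hormone gene Pmch (16.6- and 3.53-fold), Prok2 (3.27- and 1.88-fold), the osteoprotegerin gene Tnfrsf11b (5.13- and 2.63-fold) and the collagen genes Col24a1 (2.77- and 1.86-fold) and Col4a4 (1.78- and 1.71-fold) were also higher. Of their neuronal counts, sub-cluster 14 held 90.5% for Iapp, 85.7% for Csn1s1 and 73.8% for Fst. An Iapp UMI was also seen in 2.83 and 0.396% of oligodendrocyte-like cells of sated and fasted mothers, against 2.53 and 0.633% of neurons. Thinned, the shares in sated mothers were 1.01 and 1.17%. For Csn1s1 the unthinned shares were 1.26 and 0% against 1.84 and 0.882%. RNA released by other cells may thus add to the neuronal counts of sated mothers. With each neuron type weighted alike in the 4 libraries, the log2 ratios of Fst went from 3.53 and 1.85 to 3.76 and 3.36 and those of Iapp from 8.23 and 6.52 to 7.10 and 7.07. In sated mice Csn1s1 went from 7.49 to 6.70. Sub-cluster 43 was left out of that weighting, with 13 and 19 cells in the sated libraries, under the minimum of 20. It ranked next for Fst, with 21, 37, 35 and 19 counts (173, 136, 180 and 80.1 CPM). The weighted Fst values thus cover the other neurons only, and their change cannot be put down to the fixed makeup alone. Since Iapp, Csn1s1 and Fst are among the genes that define sub-cluster 14, its size is not compared. It held 1, 1, 858 and 120 Iapp counts.

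**Figure D5:**
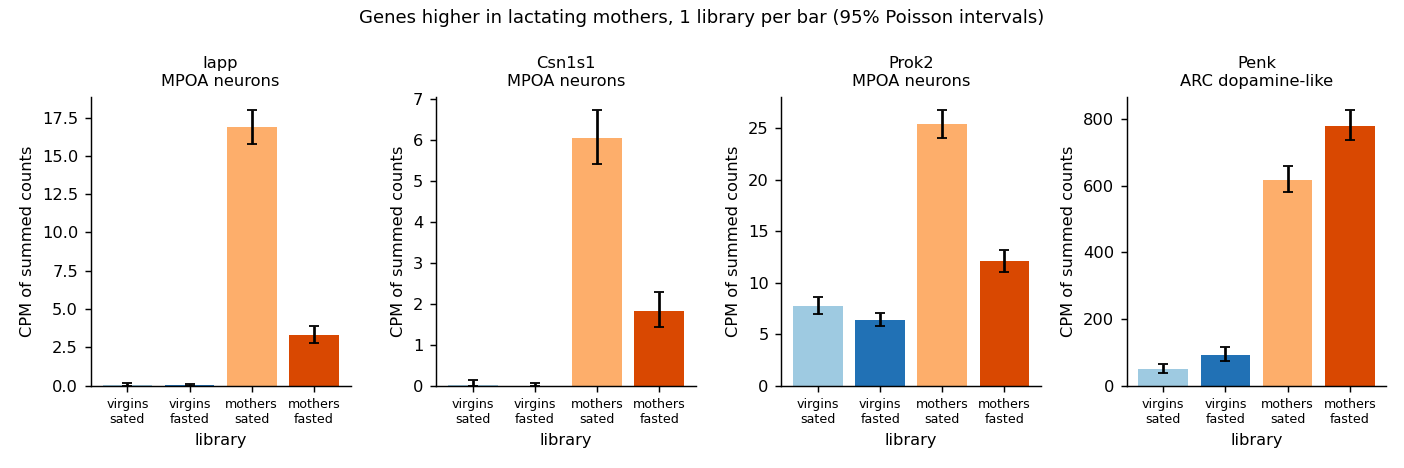
CPM of Iapp, Csn1s1 and Prok2 in MPOA neurons and of Penk in dopamine-like ARC neurons; each bar is 1 library and error bars are 95% Poisson intervals. Iapp stood at 16.9 CPM in sated mothers and 3.31 in fasted mothers against 0.0449 and 0.0290 in virgins.

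Over all MPOA neurons 30 of 14130 genes met the rule with lactation, 24 higher and 6 lower, against 46 in opposite directions and 4.86 and 0.952 for independent lists. The lower genes were the vasoactive intestinal peptide gene Vip (1.67- and 2.97-fold), Nrgn (1.66- and 1.84-fold), Tnxb (1.57- and 1.78-fold), Cbln1 (1.52- and 1.67-fold) and Slitrk6 (1.51- and 2.07-fold), and Fam90a1b (ENSMUSG00000043549; 1.86- and 1.98-fold), whose symbol 2 rows share and whose identity is uncertain. With each neuron type weighted alike in the 4 libraries, Nrgn, Tnxb and Cbln1 no longer met the rule. Thinned cells gave 7 genes, 5 of them among the 30, and subtraction of oligodendrocyte-like CPM 1157.

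By list, prolactin and STAT5 signalling had 2 of 12 members higher in mothers (median 0.11 and 0.12), the insulin-like growth factor gene Igf1 (3.89- and 1.53-fold) and Socs3 (1.59- and 2.18-fold). The reproductive axis had 1 of 8 higher (median 0.29 and -0.35), Pdyn (1.53- and 1.69-fold), with Gnrh1 next (3.18- and 1.42-fold). The appetite list had 1 of 19 higher, the activin receptor gene Acvr1c (2.75- and 1.70-fold), with Vgf next (1.35- and 1.68-fold). The parenting list had medians of 0.07 and -0.09, with Oxt (1.38- and 2.63-fold) and Pgr (1.23- and 1.37-fold) lower. Over all neurons Brs3 was 1.58-fold (1.39 to 1.78) lower in sated mothers, with no difference detectable at this depth in fasted mothers, 1.12-fold (0.997 to 1.25) lower. Sub-clusters differed under that value. In fasted mice, Brs3 was lower in mothers in sub-clusters 14 (30.6 against 102 CPM) and 19 (39.0 against 68.2). It was higher in sub-cluster 1 (93.9 against 70.9). In sated mice it was lower in mothers in sub-clusters 1 (28.7 against 65.7), 14 (36.9 against 162) and 19 (33.6 against 70.9). Dopamine synthesis had medians of -0.21 and 0.10, with Gch1 1.32- and 1.08-fold lower. In glia, the complement gene C4b (1.83- and 2.17-fold) and Zbtb16 (1.87- and 1.82-fold) were lower in astrocyte-like cells of mothers, and the connective tissue growth factor gene Ccn2 was 5.52- and 2.98-fold higher in endothelial-like cells. Genes 1.5-fold apart in the same and in opposite directions were 11 and 25 in astrocyte-like and 9 and 26 in oligodendrocyte-like cells. They were 4 and 10 in microglia-like and 14 and 7 in endothelial-like cells. Atp1b1, a sodium pump subunit gene abundant in neurons, was higher in mothers in astrocyte-like (1.82- and 1.52-fold), oligodendrocyte-like (2.08- and 1.51-fold), microglia-like (1.97- and 1.90-fold) and endothelial-like cells (2.34- and 2.07-fold) alike. The summed neuron markers were also higher in mothers in each of these classes, at 544, 563, 846 and 699 CPM in astrocyte-like, 447, 639, 741 and 789 in oligodendrocyte-like, 659, 567, 1027 and 697 in microglia-like and 767, 770.1, 1315 and 1086 in endothelial-like cells.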

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

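These results were picked because a gene of the fixed lists was at least 1.5-fold apart in opposite directions in the 2 pairs of a comparison in all neurons of a region. Differences are the second pair's log2 ratio minus the first's, and with 1 library per group none of them was tested.

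In ARC neurons 3 genes parted the pairs. The immediate early gene Fosb stood at 22.1, 9.67, 5.29 and 8.42 CPM, lower in fasted than sated virgins and higher in fasted than sated mothers, a difference of 1.86 for fasting. The lipoprotein lipase gene Lpl stood at 1.86, 4.53, 3.62 and 2.35 CPM, a difference of -1.90 for fasting and for lactation alike, since both are made from the same 4 libraries. The dopamine transporter gene Slc6a3 stood at 9.92, 5.97, 5.45 and 12.5 CPM, a difference of 1.92 for both comparisons.

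In MPOA neurons the vasopressin gene Avp stood at 0.652, 40.3, 62.6 and 0.760 CPM, a difference of -12.27 for fasting and for lactation. Magnocellular-like neurons held 77.6% of its neuronal counts, with 22, 1581, 3309 and 7 Avp counts in 38, 52, 27 and 11 cells, and sub-cluster 39 held 15.9%, with 0, 1011, 0 and 0 counts. Npy stood at 7.50, 3.05, 3.25 and 10.1 CPM, a difference of 2.93, and the urocortin gene Ucn3 at 2.76, 1.31, 0.554 and 1.96 CPM, a difference of 2.89, each for fasting and for lactation. Trh, the thyrotropin-releasing hormone gene, stood at 42.0, 57.8, 70.8 and 36.0 CPM, a difference of -1.44 for lactation.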

How the results depend on the processing

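A fixed makeup of neuron types and leaving out sub-clusters held mostly by 1 library were chosen after the results were seen, and the 12 values they gave for the main results stayed within their limits. No paired analysis was run, because no result here comes from a test and so there was no fit to take a replicate block. The pairs of virgins and of mothers are given side by side instead, and a model of feeding with reproductive state as a block was not run. Of the alternatives fixed in advance, 99 values of the main results stayed within their counting interval, or within 1.5 times for a count of genes, and 33 lay outside it without a change of direction. Counting intervals are narrow at this depth, so small shifts lie outside them. The values are log2 ratios, and the cause was not tested unless stated.

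Agrp in AgRP-like neurons, fasted against sated virgins, was 1.76 as reported, 1.86 with TMM factors, 1.86 with DESeq2 size factors, 1.65 as a mean of per-cell CPM and 1.62 with cells thinned to 2000 UMIs. Scaling factors shift each gene of a pair of libraries alike. In mothers it was 0.20 as reported, 0.14 as a mean of per-cell CPM and 0.11 thinned. Agrp in sated mothers against sated virgins was 1.33 as reported and 1.40 with DESeq2 size factors. In fasted mothers against fasted virgins it was -0.22 as reported, -0.28 with DESeq2 size factors, -0.13 as a mean of per-cell CPM, -0.28 with all variable genes as clustering features and -0.17 thinned. Pomc in POMC-like neurons, fasted against sated mothers, was -0.85 as reported and -0.96 as a mean of per-cell CPM, and Brs3 in MPOA neurons of fasted against sated mothers 0.47 as reported and 0.69 with oligodendrocyte-like CPM subtracted.

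Counts of genes that met the size rule are given for ARC fasting, ARC lactation, MPOA fasting and MPOA lactation. They were 151, 21, 20 and 7 with thinned cells (124, 8, 14 and 5 of them shared with the report's), where fewer genes reach 400 counts, 76, 10, 8 and 5 at 2-fold, 602, 160, 236 and 116 with at least 100 counts and 2835, 2098, 2340 and 1977 with no filter, where more genes enter. Subtracting the CPM of oligodendrocyte-like cells gave 2267, 1751, 1415 and 1157. That subtraction sets genes at or below their level in those cells to 0, so it makes large ratios of genes that neurons and oligodendrocytes share.

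Of the list medians, 2 turned direction under that subtraction: heat shock in ARC astrocyte-like cells of fasted against sated mothers, to 1.17, and glucocorticoid response in MPOA neurons of fasted against sated virgins, to -0.63. A further 263 of 308 list medians lay outside their tolerance of 0.1 log2 under it, and 61 of 408 with TMM factors. Of 32 class shares, 3 lay outside their interval with all variable genes as features, 20 with the stricter cell filter, 8 with at most 10% mitochondrial UMIs and 8 with doublets kept. Depth limits the smaller classes most, since a gene needs 400 counts over 4 libraries to be compared.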

Other observations

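The tests of RNA released by other cells, of the time of collection and of fasting genes chosen in virgins were chosen only after the results were seen. So were the genes of the next 2 paragraphs.

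Socs2 and Cish, both targets of prolactin signalling, stood highest in sated mothers in dopamine-like and KNDy-like ARC neurons, but not in AgRP-like neurons. In dopamine-like ARC neurons Socs2, a feedback inhibitor of STAT5 signalling, stood at 43.8, 48.5, 266 and 67.9 CPM and Cish, another such target, at 24.3, 16.2, 78.6 and 15.8 CPM, so that Socs2 was 6.07-fold (4.46 to 8.44) higher in sated mothers than in sated virgins and 3.91-fold (3.15 to 4.90) lower in fasted than in sated mothers. In KNDy-like neurons Socs2 stood at 106, 83.1, 437 and 116 CPM, 4.11-fold (3.59 to 4.73) higher in sated mothers than in sated virgins and 3.77-fold (3.29 to 4.34) lower in fasted than in sated mothers, and Cish at 14.4, 22.9, 62.6 and 48.3 CPM. In AgRP-like neurons Socs2 stood at 99.9, 91.1, 108 and 121 CPM and Cish at 19.3, 8.59, 12.7 and 17.8 CPM. The prolactin receptor gene Prlr stood at 1198, 1326, 1588 and 1214 CPM in the dopamine-like neurons. In GHRH-like neurons Ghrh, which encodes growth hormone-releasing hormone, was 2.79-fold (2.45 to 3.18) and 2.01-fold (1.81 to 2.23) lower with fasting, at 656, 235, 508 and 253 CPM.

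In tanycyte-like cells the interferon response list had medians with fasting of -1.40 and -0.78, with 6 of 9 members at least 1.5-fold lower in both pairs, among them Bst2 (3.10- and 2.02-fold), Ifitm3 (3.804- and 1.98-fold) and Isg15 (3.33- and 3.09-fold). In endothelial-like cells the medians were -1.07 and -0.54 in the ARC, with 2 of 7 members lower, and -0.96 and -0.63 in the MPOA, with 4 of 8. ARC neurons had 1 of 11 members lower and astrocyte-like cells 2 of 4 in the ARC and 1 of 3 in the MPOA. Of the heat shock list, 4 of 10 members were lower in tanycyte-like cells, such as Hsp90aa1 (1.70- and 1.64-fold), with medians of -0.75 and -0.58, against -0.56 and -0.73 in ARC astrocyte-like and -0.80 and -0.42 in ARC microglia-like cells. The astrocyte-like median in mothers turned direction with oligodendrocyte-like CPM subtracted, as given above. Sterol synthesis genes of ARC astrocyte-like cells parted the pairs, with medians of -0.39 and 0.66. Oligodendrocyte precursor-like cells had Cdkn1a at 3.21, 90.2, 7.98 and 63.2 CPM in the MPOA and 4.30, 113, 2.83 and 81.6 in the ARC, where their astrocyte markers were at 1380.2, 2128, 1579.9 and 2012 CPM.

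Of the glucocorticoid response list, 13 of 14 members were at least 1.5-fold higher in oligodendrocyte-like MPOA cells of both fasted libraries. Stronger dissociation stress in the fasted pools was first read from heat shock genes. Their medians of 0.0973 in virgins and -0.487 in mothers lay under the bound of 1.5-fold, with 1 and 0 of 7 members at least 1.5-fold higher. The heat shock list also had medians below 0 with fasting in ARC neurons and in ARC astrocyte-, microglia- and tanycyte-like cells. Low heat shock medians may thus go with fasting, so they cannot exclude stronger stress. As read from immediate early genes it stays open: their median was 0.659 in virgins (percentile 99.8), with 4 of 7 members higher and 1 lower, and 0.0654 in mothers, with 2 higher and 3 lower, so the bound of 1.5-fold on that median decides nothing. Of the 13 genes, 5 (Sgk1, Klf9, Ddit4, Plin4 and Cdkn1a) had their highest level of all classes in oligodendrocyte-like cells of both fasted libraries, so RNA released by other cells stays open for the other 8. For those 5 the lowest ratio to the next class was 1.06 (0.877 to 1.30), for Klf9 against vascular leptomeningeal-like cells, an interval that includes 1, whereas Sgk1 stood 4.19 and 5.48 times above the next class, and the preparation of each pool is confounded with its group.

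Of 12 clock genes, a list chosen after the data were seen, 9 (Dbp, Tef, Hlf, Per3, Nr1d1, Nr1d2, Ciart, Bhlhe40 and Bhlhe41) were at least 1.5-fold lower with fasting in both pairs of AgRP-like neurons and 3 (Per1, Per2 and Arntl) were not, with medians over the 12 of -2.18 and -1.63. Collection at different times of day would lower Dbp, Tef and Per3 in other neurons too, but in POMC-like neurons the smaller of their 2 medians was 0.859, and the medians of 8 of the 9 with enough counts there were 0.72 and 0.70. The medians of all clock genes with enough counts were 0.48 and 1.27 in KNDy-like, -0.49 and -0.61 in dopamine-like neurons and -0.67 and -0.06 in astrocyte-like cells. A general lowering by a few abundant genes was argued against by the median of all genes in AgRP-like neurons, which was no lower than -0.0149. A different phase of the clock in each cell type, with different collection times, was not tested and stays open.

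Agrp was higher in AgRP-like neurons of sated mothers than of sated virgins. The ratio was 2.54 (2.43 to 2.66) without the sub-clusters held mostly by fasted libraries, 2.53 with cells thinned to 2000 UMIs and 2.51 with oligodendrocyte-like CPM subtracted, each above the bound of 1.5. The first and last of these values argue against fasted-type cells and free RNA as the whole cause. Thinning leaves the expected share of a gene among a cell's UMIs unchanged, so the thinned ratio decides nothing about depth. A wider difference of sated mothers along the fasting genes cannot be told apart: in genes chosen in virgins, the median of sated mothers over sated virgins was 0.0957 for the 817 higher with fasting and -0.112 for the 1010 lower, a difference of 0.208 against at most 0.0569 in 100 draws with no effect, but these genes share the sated virgins with the ratio. Genes chosen in mothers gave -0.0390 against at most -0.0137, a choice that leaves out genes already near the fasted level in sated mothers, and a difference between the single pools of 3 mice may also account for the Agrp ratio.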
